A study of Mus musculus with 32 samples.

How the data were processed

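Gene expression was measured by RNA sequencing in 32 libraries of cells sorted from mouse gliomas. Per the labels' protocols, tumours were started in XFM mice aged 5 to 6 weeks by injecting into the brain DF-1 cells, a chicken fibroblast line, that carried PDGFB, the B chain of platelet-derived growth factor. Treatment with vehicle or with BLZ945, an inhibitor of the macrophage receptor CSF-1R, began at a tumour volume of 20 to 40 cubic millimetres and was given each day until symptoms appeared or the mice were 26 weeks old. Per the labels' protocols, tumours were digested with papain, and cells bearing PDGFRA were sorted as tumour cells (TC) beside cells with CD11b and without Gr1, the tumour-associated macrophages and microglia (TAM). Libraries were made with a SMART-Seq kit, which does not mark strand, and sequenced on an Illumina instrument with 2 reads of 50 bases per fragment.

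The deposited values are whole-number counts per gene symbol, with no normalization, in a table of 23337 genes, of which 1715 had no count in any library. Reads were aligned with STAR 2.3.0e and handled with SAMtools against mm10, per the submitters' processing notes; the program that counted reads and the gene annotation are not given in the sources used here. In each of the 22 BLZ945 libraries every deposited count was even, while 47.1 to 49.5% of the counts in the vehicle libraries were even and 84929 were odd. Counting both reads of a pair would give even numbers only, so the totals of the BLZ945 libraries, 4.18 to 19.6 M, would stand for 2.09 to 9.78 M fragments, against 13.1 to 30.4 M counts in vehicle libraries. The deposited counts were used as they are, and an alternative with the BLZ945 counts halved was chosen after seeing the data. This difference between the files follows treatment, as do the mouse numbers, and stays in every comparison with vehicle.

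Groups were taken from the cell type and stage in the labels: Vehicle, Endpoint and Rebound, each for TAM and TC. The agent label reads BLZ945 in every library, Vehicle included, so treatment was read from the stage; BLZ945 libraries are those of Endpoint and Rebound. The labels also call the Endpoint tumours dormant and give no further definition of Rebound. Samples are named by group and mouse number; replicates are different mice, and 15 of the 17 mice gave both a TAM and a TC library. No pair of libraries within a group agreed within sampling noise (the lowest chi-square per degree of freedom was 11.1). Of the symbols, 20953 were found in GENCODE M21, from which the coordinates in GRCm38 (mm10) were taken, and 2384 were not.

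Differential expression was tested with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr, TMM scaling, estimateDisp, glmQLFit with robust=TRUE and glmQLFTest, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 16 libraries of a cell type entered one fit, so the 3 stages share one estimate of spread. TAM versus TC, and the difference between TAM and TC in each stage contrast, came from a fit of 6 groups over all 32 libraries. Standard errors of log2 fold changes come from the quasi-likelihood F statistic. Levels are CPM after TMM scaling in each fit, with SD over libraries. The adjusted p printed beside a single gene is from edgeR unless another tool is named.

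The 31 gene lists and 13 lists of cell type markers were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the alternatives listed here, except those named as added. Lists with at least 5 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a contrast. The adjusted p with an estimated correlation is given beside each call: of the list calls in the 6 stage contrasts, 0 hold with it, against 15, 13, 21, 13, 12 and 16 calls at the preset value and 14, 10, 20, 15, 3 and 14 with fry, which tests whether a list's genes move, on balance, one way. For every called list the median, the mean and the test had the same sign. Members were also counted after adjustment over the list alone. Marker lists were compared as the mean log2 CPM of their genes, by exact two-sided permutation tests adjusted over 78 tests; the smallest p these allow is 0.00216 for 6 against 5 mice and 0.00794 for 5 against 5. Marker symbols without a match in the table (Trac, Trbc2, Ighm, Igkc, Ly6g and Hbb-bt) were left out.

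The lists cover IGF ligands and receptors, PI3K-AKT-mTOR components, FOXO-induced genes, alternative (M2-like) activation, the IL-4 and STAT6 response, NFAT and calcineurin, inflammatory genes, type I interferon and interferon gamma responses, MHC classes I and II, homeostatic and disease-associated microglia, monocyte-derived macrophages, lysosome, CSF1R ligands and survival cytokines, G1/S, G2/M, p53 targets, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, ribosomal proteins, extracellular matrix, TGF-beta, the unfolded protein response, immediate early genes, oligodendrocyte progenitor and proneural, mesenchymal and neural stem genes, and PDGF receptors with ligands of other receptor tyrosine kinases. Named genes are the 8 highest and the 8 lowest of each contrast among called genes with an absolute log2 fold change of at least 1, a mean log2 CPM of at least 3, and every library of each group on its side of the other group's median, without unnamed gene models. To these come preset genes of each cell type, up to 3 called members of each called list by smallest adjusted p and, for TAM versus TC, the myeloid and tumour cell markers. The text gives values for a subset of them, and 1 preset gene is not reported here; within this rule the number of mice on the side of the change is the whole group unless stated.

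The tests were run first on simulated counts with 200 changed genes. Of genes changed 4-fold, 98.5, 88.1 and 92.5% were recovered in TAM Endpoint versus Vehicle, Rebound versus Vehicle and Rebound versus Endpoint (12661, 12685 and 12761 genes), and 71.6, 70.1 and 71.6% in the same TC contrasts (14111, 14111 and 14130 genes). Of genes changed 2-fold, 41.8, 43.3 and 46.3% were recovered in TAM and 8.96, 7.46 and 7.46% in TC. The biological coefficient of variation was 0.425 in TAM and 0.664 in TC.

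Relations across mice were computed over the 15 mice with both libraries, as Pearson's r and Spearman's rho with two-sided permutation tests of 1e+05 resamples (exact within Endpoint), adjusted over 3 relations. Because TAM and TC libraries come from the same animals, a fit with the mouse as a block was made with limma duplicateCorrelation over all 32 libraries. Deviations from the group means correlated between the libraries of a mouse by 0.011 to 0.337 (median 0.066), 5 of 15 mice were above 0.1, 10 of 15 matched their own mouse best, and the consensus correlation was 0.135. Alternatives chosen in advance were RLE size factors, DESeq2 1.42.0, limma voom with quality weights, no filter on low counts, at least 5 CPM in at least 5 libraries, an absolute log2 fold change of at least 1, robust=FALSE, a fit of only the 2 stages compared or of all 32 libraries, removal of genes over 8-fold higher in the other cell type, an estimated correlation or fry for lists, the mouse block for genes, and each library left out in turn. Added after seeing the data were the mouse block for lists (cameraPR), the halved counts, 3 marker means as covariates (T and NK, pericyte and fibroblast, and tumour cell in TAM, and T and NK, choroid plexus and myeloid in TC), and the omission of 3 TAM libraries with a T and NK marker mean above 1 (Rebound 49041, 49059 and 49849) and of 5 TC libraries above 5 (Endpoint 49823, 49825, 49830 and 49831, Rebound 49827). Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.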

Results

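RNA was sequenced from 2 cell populations sorted from mouse gliomas at 3 stages of treatment with the CSF-1R inhibitor BLZ945: tumour-associated macrophages and microglia (TAM) and PDGFRA-bearing tumour cells (TC). The TAM libraries came from 5 Vehicle mice (54359, 54363, 57098, 57682 and 64247), 6 Endpoint mice (49823, 49825, 49830, 49831, 49843 and 49845), whose tumours the labels call dormant, and 5 Rebound mice (49041, 49059, 49827, 49834 and 49849). The TC libraries came from the same Vehicle and Endpoint mice and from 5 Rebound mice, with 49692 in place of 49834. Total counts were 25.6 to 30.4 M in TAM Vehicle, 9.54 to 15.8 M in TAM Endpoint and 15.4 to 19.6 M in TAM Rebound. They were 13.1 to 23 M in TC Vehicle, 4.18 to 14.0 M in TC Endpoint and 10.5 to 16.5 M in TC Rebound. The ribosomal precursor Rn45s took 0.391 to 7.66, 3.69 to 6.54 and 3.15 to 4.54% of the counts in the TAM groups and 0.875 to 11.1, 6.35 to 16.9 and 5.15 to 7.15% in the TC groups, in the same order. TAM Igf1 (chromosome 10, 87858265 to 87937042, plus strand) and TC Igf1r (chromosome 7, 67952827 to 68233668, plus strand; both protein coding, GRCm38/mm10) are the ligand and receptor named in the title of the series.

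The sort was examined first through genes that separate macrophages from tumour cells. Csf1r, the colony stimulating factor 1 receptor, was 9174 ± 4475 CPM in TAMs and 207 ± 290 in TCs (SD, n = 16 each, joint scaling, log2 fold change 6.41, SE 0.472, edgeR adjusted p = 6.64e-13). The integrin subunit Itgam and the fractalkine receptor Cx3cr1 were higher in TAMs by 6.39 and 6.34 on the log2 scale. Pdgfra, the receptor used for the tumour cell gate, was 9.62 ± 11.3 CPM in TAMs and 1054 ± 996 CPM in TCs (log2 fold change -6.66, SE 0.528, edgeR adjusted p = 4.17e-12). The oligodendrocyte lineage factor Olig2 and the proteoglycan Ncan were lower in TAMs, at -5.92 and -5.21. All 16 myeloid markers rose and all 12 tumour cell markers fell in TAMs, with the leukocyte gene Ptprc (2.60) and the progenitor filament Nes (-2.05) moving least. Of 15668 genes, 10714 differed, 4528 higher and 6186 lower in TAMs.

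Markers of other cell types moved with stage in both sorts. In TC libraries, ependymal and choroid plexus markers averaged 6.83 ± 1.37 log2 CPM at Endpoint (n = 6) against 1.48 ± 0.97 in Vehicle and 1.41 ± 1.95 at Rebound (n = 5 each; exact permutation test, adjusted p = 0.0187 for both). Tumour cell markers averaged 4.80 ± 1.30 at Endpoint, 8.11 ± 0.43 in Vehicle and 8.22 ± 0.63 at Rebound (exact permutation test, adjusted p = 0.0281 for both; Rebound against Vehicle 0.814). Myeloid markers in TCs were 7.51 ± 0.98 at Endpoint, 5.77 ± 1.18 in Vehicle (adjusted exact p = 0.0337) and 2.90 ± 2.23 at Rebound (0.0281 against Endpoint). T and NK cell markers in TCs were 5.16 ± 3.86 at Endpoint and -0.67 ± 0.39 in Vehicle (adjusted exact p = 0.0511), and B cell markers 1.71 ± 2.81 and -1.51 ± 0.81 (0.0675). Erythroid markers were 1.81 ± 0.98 at Endpoint and -0.28 ± 1.18 in Vehicle (0.0409), and neutrophil markers -2.02 ± 0.17 at Rebound and 0.06 ± 1.04 in Vehicle (0.0307). In TAM libraries, astrocyte markers were 4.82 ± 0.31 at Endpoint against 3.07 ± 0.47 in Vehicle (adjusted exact p = 0.0187), neuron markers 1.25 ± 0.41 against -0.21 ± 0.36 (0.026) and dendritic cell markers 2.95 ± 0.49 against 4.11 ± 0.25 (0.0187). Endothelial markers averaged -1.06 ± 0.44 at Endpoint, -0.07 ± 0.32 in Vehicle and 1.17 ± 0.89 at Rebound.

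**Figure D1:**
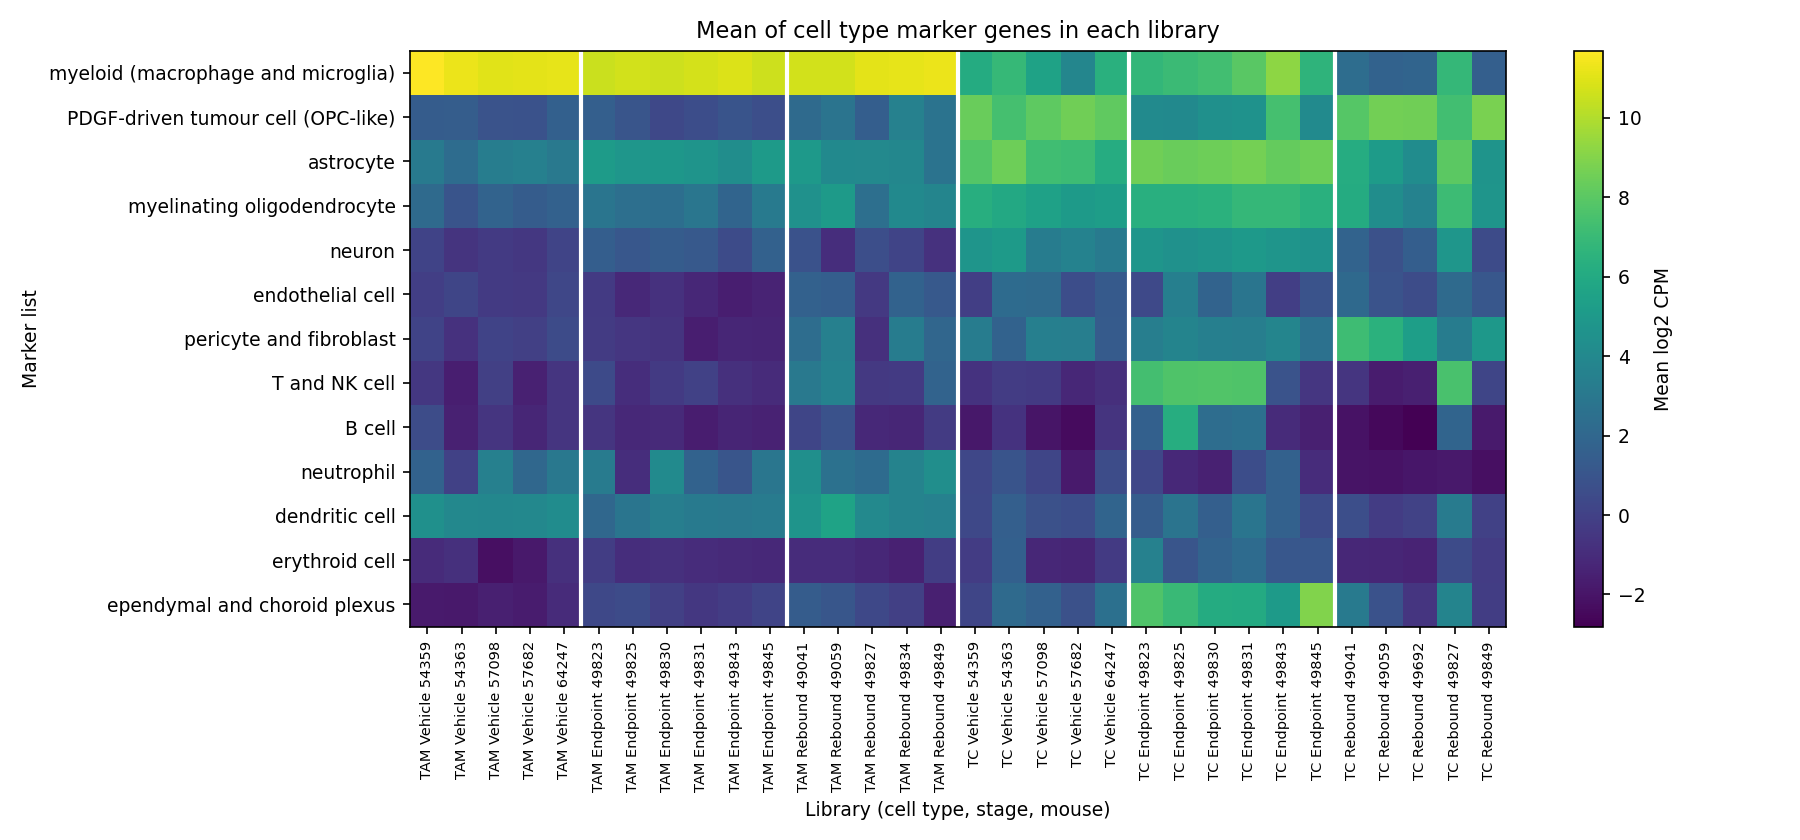
Heat map of the mean log2 CPM of 13 lists of cell type markers (vertical) in each of the 32 libraries (horizontal, by group and mouse). The TC Endpoint libraries show choroid plexus markers at 6.83 on average against 1.48 in TC Vehicle, and TC Rebound 49827 shows T and NK cell markers at 7.515.

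The comparison of Endpoint with Vehicle TAMs asks how macrophages of tumours held under CSF-1R inhibition differed from those of tumours given vehicle. Genes of alternative activation were among those lower at Endpoint. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, was 49.4 ± 22.7 CPM at Endpoint and 2382 ± 1536 CPM in Vehicle (SD, n = 6 and 5; log2 fold change -5.59, SE 0.474, edgeR adjusted p = 1.01e-06). Arg1, the arginase of alternatively activated macrophages, was 1.22 ± 0.53 against 81.1 ± 74.1 CPM (-6.05, SE 0.998, adjusted p = 0.000415). The matrix protein gene Fn1 was 23.7 ± 24.5 against 974 ± 655 CPM (-5.36, SE 0.867, adjusted p = 0.000362) and the lipoxygenase Alox15 2.80 ± 2.61 against 79.5 ± 60.2 CPM (-4.84, SE 1.05, adjusted p = 0.0027). The IL-4 receptor Il4ra fell from 1020 ± 576 to 183 ± 29.98 CPM (-2.48, SE 0.268, adjusted p = 4.95e-06). Ccr2, a chemokine receptor of monocytes, fell from 220 ± 314 to 17.4 ± 14.3 CPM (-3.65, adjusted p = 0.0054), and the purinergic receptor P2ry12 of resting microglia from 2942 ± 976 to 1198 ± 172 CPM (-1.30, adjusted p = 0.00237).

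Csf1r, the drug target, was 7152 ± 756 CPM at Endpoint and 10890 ± 3733 CPM in Vehicle (log2 fold change -0.61, SE 0.203, edgeR adjusted p = 0.0274). The mannose receptor Mrc1 was 9.95 ± 2.94 against 29.99 ± 23.5 CPM (-1.59, SE 0.521, adjusted p = 0.0274). The adjusted p for Csf1r was 0.119 without Vehicle 54359 (difference -0.36), 0.0503 to 0.0563 without Endpoint 49823, 49825, 49831 and 49843 (-0.57 to -0.60), and 0.272 with the mouse as a block (-0.68; range over alternatives 0.0129 to 0.449). That for Mrc1 was 0.0956 and 0.075 without Vehicle 57098 and 57682 (-1.15 and -1.36), 0.0542 without Endpoint 49831 (-1.44) and 0.144 with the block (-1.33; 0.00348 to 0.22). Igf1 was 23.2 ± 38.9 CPM at Endpoint and 44.8 ± 24.2 CPM in Vehicle (-0.96, SE 0.747, adjusted p = 0.349). Of the Endpoint libraries, 5 of 6 lay at 4.76 to 12 CPM and 49843 at 102.3 CPM. Without that library the Igf1 difference was -2.62 (adjusted p = 0.000114), and with the block -2.03 (0.00559, range 0.000114 to 0.561).

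Genes higher in Endpoint TAMs included Fbn2, a fibrillin, at 60.1 ± 14.0 against 2.07 ± 1.29 CPM (log2 fold change 4.87, SE 0.384, edgeR adjusted p = 2.52e-07). The glutamate transporter Slc1a2 was 129 ± 45 against 14.0 ± 4.11 CPM (3.21) and the peptide-processing enzyme Cpe 149 ± 48.2 against 18.2 ± 5.63 CPM (3.04). Slc1a2 is also an astrocyte gene, and astrocyte markers were 4.82 against 3.07 log2 CPM in these libraries. Ttr, the thyroid hormone carrier of the choroid plexus, was 82.8 ± 30.2 against 1.72 ± 1.34 CPM (5.57, adjusted p = 0.00139; 0.243 with the block, range over alternatives 6.67e-09 to 0.243), while choroid plexus markers were 0.04 against -1.56 log2 CPM. The lysophospholipase Enpp2 was higher by 4.09 (0.069 with the block, range 1.57e-11 to 0.069). Of 13315 genes tested, 4390 were called, 1821 higher and 2569 lower.

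Of 31 gene lists, 15 passed camera in Endpoint against Vehicle TAMs, all of them lower. Myeloid markers were also lower, at 10.68 ± 0.16 against 11.25 ± 0.26 log2 CPM (exact permutation test, adjusted p = 0.026), and myelinating oligodendrocyte markers higher, at 2.60 ± 0.45 against 1.61 ± 0.47 (0.0337). Among 30 genes of glycolysis and hypoxia 24 fell and 1 rose (25 and 1 adjusted over the list alone, median log2 fold change -1.48, camera adjusted p = 1.95e-08). The glucose transporter Slc2a1 was 37.0 ± 5.34 against 203 ± 47.7 CPM and the pyruvate kinase Pkm2 625 ± 313 against 3018 ± 1040 CPM. Among 22 alternative activation genes 13 fell and 1 rose (16 and 1 over the list, median -2.66, 3.41e-05), among them the scavenger receptor Stab1 (-2.39). Of 26 genes of monocyte-derived macrophages 15 fell (16 over the list, median -1.67, 2.4e-05), with the secreted matrix protein Tgfbi at -3.66 and the lysozyme Lyz2 at -1.54. Of 26 disease-associated microglia genes 14 fell (16 fell and 2 rose adjusted over the list, median -1.41, 3.41e-05), with the growth factor Csf1 at -3.17 and the protease Ctsb at -1.52. Of 32 lysosome genes 18 fell and 1 rose (19 and 2 over the list, median -0.80, 7.55e-05). Of 12 MHC class II genes 7 fell (7 over the list, median -1.52, 0.000394). H2-Ab1 was 130 ± 54.8 against 1674 ± 372 CPM and Cd74, the invariant chain, 2217 ± 392 against 8250 ± 3257 CPM, while dendritic cell markers were 2.95 against 4.11 log2 CPM. Of 28 inflammatory genes 13 fell and 1 rose (15 and 1 over the list, median -0.93, 0.00051), with the cytokines Il1b (-2.67) and Tnf (-3.58). Of 22 mesenchymal glioma genes 14 fell and 2 rose (15 and 2 over the list, median -1.22, 7.55e-05), with the annexin Anxa2 at -4.27. Of 26 PDGF receptor and receptor tyrosine kinase genes 9 fell and 3 rose (9 and 3 over the list, median -0.72, 0.0451), with the ERK phosphatase Dusp6 at 63.5 ± 14.1 against 814 ± 178 CPM. Each of these 9 lists had an adjusted p of 0.539 with an estimated correlation.

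The IL-4 and STAT6 list was lower in Endpoint TAMs with 10 of 22 genes down and 1 up (12 and 1 adjusted over the list alone, median -1.53, camera adjusted p = 0.0108; adjusted p = 0.57 with an estimated correlation), among them the lectin Clec10a (-3.57) and Stat6 (-1.31). Another 5 lists had an adjusted p of 0.667 with an estimated correlation. Among 26 interferon gamma genes 15 fell (17 over the list, median -1.38, camera adjusted p = 0.000595), with the class II activator Ciita at -3.88. Among 33 type I interferon genes 14 fell and 1 rose (15 and 1 over the list, median -0.82, 0.0104), with Irf7 at -2.41. Of 17 MHC class I genes 7 fell (7 over the list, median -0.47, 0.0377). Of 25 homeostatic microglia genes 12 fell (14 fell and 1 rose adjusted over the list, median -0.73, 0.00586), with the fructose transporter Slc2a5 at -2.06. Of 25 immediate early genes 9 fell (9 over the list, median -0.69, 0.0166), with Atf3 at -2.53. The call for type I interferon was lost without Vehicle 57098 (adjusted p = 0.132) and by fry (0.127; range over alternatives 0.000803 to 0.667). That for MHC class I was lost without Vehicle 54359 (0.0817), Vehicle 57098 (0.212) or Endpoint 49845 (0.0557), by fry (0.0923), without genes of the other cell type (0.0588) and with the block (0.255, range 0.00226 to 0.667). That for the PDGF list was lost without 4 of the 11 libraries (0.0506 to 0.072), with halved counts (0.0592), without genes of the other cell type (0.0588) and with the block (0.247, range 0.00201 to 0.539), and that for IL-4 with the block (0.0504; range 0.00368 to 0.57). Extracellular matrix (0.0505) and the other 15 lists did not pass; 7 PI3K-AKT-mTOR genes rose and 9 fell (9 and 10 over the list, camera adjusted p = 0.905).

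Rebound TAMs were set against Vehicle TAMs to ask what distinguished macrophages of Rebound tumours from those of tumours given vehicle. Igf1, the growth factor named in the series title, was 357 ± 79.0 CPM at Rebound and 44.8 ± 24.2 CPM in Vehicle (SD, n = 5 each; log2 fold change 2.99, SE 0.833, edgeR adjusted p = 0.0272), at 271 to 485.8 CPM in the Rebound libraries. Clec7a, the receptor dectin-1, was 1029 ± 281 against 115 ± 56.6 CPM (3.17, SE 0.418, adjusted p = 0.000274). Hmox1 was 188 ± 107 against 2382 ± 1536 CPM (-3.67, SE 0.468, adjusted p = 0.000271). Slc2a5 was 92.2 ± 50.3 against 911 ± 200 CPM (-3.31, SE 0.299, adjusted p = 6.53e-06) and the serine synthesis enzyme Phgdh 18.6 ± 3.58 against 120 ± 45.7 CPM (-2.69, SE 0.282, adjusted p = 3.31e-05). P2ry12 fell from 2942 ± 976 to 872 ± 406 CPM (adjusted p = 0.00187), Il4ra from 1020 ± 576 to 394 ± 100 CPM (0.00397), and Csf1r from 10890 ± 3733 to 4520 ± 914 CPM (-1.27, 0.00136; 0.0558 with the block, range over alternatives 3.68e-07 to 0.226). Cd74 was 24780 ± 16170 against 8250 ± 3257 CPM, higher in 4 of 5 Rebound libraries (1.59, 0.016).

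Some of the rises in Rebound TAMs were of genes that other cells also express. Enpp2, also made by oligodendrocytes, was 124 ± 98.9 against 2.66 ± 1.72 CPM (log2 fold change 5.53, edgeR adjusted p = 0.000271), while myelinating oligodendrocyte markers averaged 4.0 ± 0.97 against 1.61 ± 0.47 log2 CPM (exact permutation test, adjusted p = 0.0307). Postn, the matrix protein periostin, was 51.5 ± 30.5 against 3.92 ± 1.6 CPM (3.71, 0.000116), and pericyte and fibroblast markers were 2.07 ± 1.74 against -0.02 ± 0.45 (adjusted exact p = 0.0884). T and NK markers were 1.55 ± 1.88 against -0.84 ± 0.67 (0.0794). Of 13315 genes 1961 were called, 932 higher and 1029 lower, and 525 were called without the 3 Rebound libraries with T and NK markers. The Igf1 difference was then 2.92 (adjusted p = 0.16) and that of Cd74 0.92 (0.218; 0.271 with the block; range over alternatives 0.000605 to 0.271). The adjusted p for Igf1 was also above 0.05 without Vehicle 54359 (0.0548), 54363 (0.0605), 57098 (0.0557) or 64247 (0.0598) or Rebound 49041 (0.0523), with differences of 2.74 to 3.26 when any one library was left out (range of adjusted p over alternatives 6.74e-06 to 0.341).

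Arg1 was 440 ± 480 CPM in Rebound and 81.1 ± 74.1 CPM in Vehicle TAMs, higher in 4 of 5 (log2 fold change 2.44, SE 0.871, edgeR adjusted p = 0.0738), and Mrc1 66.3 ± 33.5 and 29.99 ± 23.5 CPM (1.14, 0.169). Without Vehicle 57682 or Rebound 49834 Arg1 passed (3.06 and 2.76, adjusted p = 0.047 and 0.0373), and without the 3 libraries with T and NK markers it was -0.54 (0.756; range over alternatives 0.023 to 0.756). Ccr2 was 228 ± 188 and 220 ± 314 CPM (0.06, SE 0.847, adjusted p = 0.973); its sign turned without 6 of the 10 libraries (down to -0.42).

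By camera 7 lists were lower in Rebound against Vehicle TAMs. Of 34 G2/M genes 24 fell (27 adjusted over the list alone, median -1.63, camera adjusted p = 1.25e-13), with the mitotic kinases Plk1 at 7.05 ± 1.96 against 56.8 ± 33.1 CPM and Aurka at -2.33. Of 31 G1/S genes 1 fell, with none passing when adjusted over the list (-0.66, 0.00308). Of 25 homeostatic microglia genes 15 fell (18 over the list, median -1.26, 1.34e-11), with the leukotriene synthase Ltc4s at -1.81. Of 30 glycolysis and hypoxia genes 8 fell (15 over the list, median -0.75, 7.34e-05), with Slc2a1 at -1.01. Oxidative phosphorylation (5 of 38 fell, 5 over the list, median -0.22, 0.00266), ribosomal proteins (1 of 38 fell; -0.36, 0.00266) and lysosome genes (6 of 32 fell and 1 rose, 7 and 2 over the list, median -0.25, 0.0295) were also lower. The adjusted p with an estimated correlation was 0.256 for homeostatic microglia, 0.339 for G2/M and glycolysis, 0.842 for G1/S and 0.795 for the other 3. By fry the p was 0.422 for G1/S, 0.243 for lysosome and 0.233 for oxidative phosphorylation and ribosomal genes. The lysosome call was lost without Vehicle 54359 (0.2), Rebound 49041 (0.0955) or Rebound 49059 (0.179), without the 3 libraries with T and NK markers (-0.12, 0.537) and without genes of the other cell type (0.0801; range over alternatives 0.00624 to 0.795).

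Lists of the IGF system and of matrix and tumour-related genes rose in Rebound against Vehicle TAMs. Of 13 IGF ligands, receptors and binding proteins 4 rose (5 adjusted over the list alone, median 0.82, camera adjusted p = 0.00325; adjusted p = 0.216 with an estimated correlation), among them Igf1. The scavenging receptor Igf2r was 24.2 ± 7.67 against 3.90 ± 2.04 CPM (2.63). Of 22 FOXO-induced genes 6 rose (6 over the list, median 0.50, 0.0149; adjusted p = 0.371 with an estimated correlation), with the stress gene Gadd45a at 2.42. Of 27 extracellular matrix genes 12 rose and 1 fell (14 and 1 over the list, median 1.69, 8.75e-05; adjusted p = 0.339 with an estimated correlation), with the protease Mmp14 at 1.69. Of 19 oligodendrocyte progenitor and proneural genes 11 rose (15 over the list, median 2.29, 1.93e-08), with the kinase Fyn at 2.32. Of 19 neural stem genes 5 rose (5 over the list, median 0.71, 0.00835), with the tubulin Tubb3 at 2.47 (adjusted p = 0.256 with an estimated correlation for both). Tumour cell markers in these TAM libraries averaged 2.55 ± 0.75 against 1.25 ± 0.37 log2 CPM (adjusted exact p = 0.0413). Of 25 immediate early genes 8 rose and 1 fell (8 and 2 over the list, median 0.69, 0.0295; adjusted p = 0.795 with an estimated correlation), with Egr1 at 133 ± 104 against 27.6 ± 13.9 CPM. Without the 3 T and NK libraries the IGF median was 0.55 (adjusted p = 0.0826, range over alternatives 0.000396 to 0.216). FOXO was then at 0.32 (0.597, 0.00355 to 0.597) and matrix at 1.79 (0.0513, 3.37e-10 to 0.339). Immediate early genes were then at -0.14 (0.34, 0.000408 to 0.795). Without genes of the other cell type the neural stem median was 0.36 (adjusted p = 0.184; range 0.00237 to 0.256) and that of the IGF list 0.68 (0.0829). FOXO also missed without Rebound 49041 (0.0501), and immediate early genes without 5 of the 10 libraries (0.0501 to 0.289) and by fry (0.233). The other 18 lists did not pass (0.0659 to 0.953), among them NFAT and calcineurin, with 2 genes up and 1 down (4 and 1 over the list, median 0.141).

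Rebound and Endpoint TAMs, both from BLZ945-treated mice, were compared to ask what changed between these 2 stages. Igf1 was 357 ± 79.0 CPM at Rebound and 23.2 ± 38.9 CPM at Endpoint (SD, n = 5 and 6; log2 fold change 3.95, SE 0.81, edgeR adjusted p = 0.00403). Arg1 was 440 ± 480 against 1.22 ± 0.53 CPM (8.49, SE 1.09, adjusted p = 0.000217). Alox15 was 368 ± 405 against 2.80 ± 2.61 CPM (7.05, 0.000943), the surface protein gene Cd24a 191 ± 200 against 1.59 ± 0.716 CPM (6.87, 0.000345) and Fn1 894 ± 522 against 23.7 ± 24.5 CPM (5.24, 0.00107). Mrc1 rose by 2.73 (0.00258), Ccr2 by 3.71 (0.00977), Il4ra by 1.11 (0.00628) and Cd74 by 3.48 (4.07e-05). Fbn2 fell from 60.1 ± 14.0 to 7.38 ± 3.05 CPM (-3.02, 3.51e-05), the IGF-binding protein Igfbp4 from 46.5 ± 11.1 to 6.05 ± 2.69 CPM (-2.94, 6.71e-05) and the cyclin Ccnb2 from 92.5 ± 14.5 to 16.1 ± 10.5 CPM (-2.53, 0.00101). Csf1r was 4520 ± 914 against 7152 ± 756 CPM (-0.66, 0.0318) and P2ry12 872 ± 406 against 1198 ± 172 CPM, above the Endpoint median in 1 of 5 (-0.46, 0.305).

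Of 13315 genes tested between Rebound and Endpoint TAMs 2337 were called, 1552 higher and 785 lower. Without the 3 libraries with T and NK markers 592 were called. The adjusted p was then 0.0638 for Igf1 (3.90; range over alternatives 3.15e-07 to 0.378), 0.145 for Mrc1 (1.73; 2e-07 to 0.439), 0.304 for Ccr2 (2.13; 8.06e-05 to 0.537) and 0.142 for Il4ra (0.91; 0.00058 to 0.808). The Csf1r call was lost without Endpoint 49823, 49830, 49831 or 49845 (adjusted p = 0.0501 to 0.0633) or Rebound 49059 (0.085), at differences of -0.54 to -0.67, and with the block (-0.67, 0.376; range 0.00492 to 0.742). In these libraries dendritic cell markers averaged 4.30 ± 0.84 at Rebound and 2.95 ± 0.49 at Endpoint (adjusted exact p = 0.0187), pericyte and fibroblast markers 2.07 ± 1.74 and -0.93 ± 0.51 (0.0307). Endothelial markers were 1.17 ± 0.89 and -1.06 ± 0.44 (0.026) and tumour cell markers 2.55 ± 0.75 and 0.86 ± 0.42 (0.026).

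Activation lists rose between Endpoint and Rebound TAMs. Of 22 alternative activation genes 15 rose (17 adjusted over the list alone, median 2.86, camera adjusted p = 1.09e-09). Of 22 IL-4 and STAT6 genes 13 rose and 1 fell (14 and 1 over the list, median 2.23, 5.64e-07), with Clec10a at 3.64 and the VEGF receptor Flt1 at 3.81. Of 28 inflammatory genes 18 rose (21 over the list, median 1.20, 5.84e-09), with Il1b at 3.70. Of 27 matrix genes 17 rose (20 over the list, median 4.06, 5e-10), with Postn at 3.20. Of 13 CSF1R ligands and survival cytokines 4 rose and 1 fell (5 and 1 over the list, median 0.43, 0.0109), with the stem cell factor receptor Kit at 6.33. Oligodendrocyte progenitor genes (15 of 19 rose, 16 over the list, median 3.0, 4.6e-09), with the lineage factor Sox10 at 3.17, and neural stem genes (7 of 19, 8 over the list, median 1.32, 0.00155) rose as well. These 7 lists had an adjusted p of 0.127 with an estimated correlation. Without the 3 T and NK libraries the CSF1R ligand list missed (median 0.59, 0.0595, range over alternatives 0.000199 to 0.127).

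Of 26 monocyte-derived genes 18 rose in Rebound against Endpoint TAMs (20 adjusted over the list alone, median 2.24, camera adjusted p = 1.72e-11), with Lyz2 at 2.23 and the calcium-binding S100a6 at 3.15. Of 26 disease-associated genes 17 rose (20 over the list, median 1.88, 2e-10), with Clec7a at 2.29. Of 12 MHC class II genes 8 rose (8 over the list, median 1.76, 6.1e-07), with H2-Aa at 3771 ± 2782 against 96.6 ± 58.2 CPM. Of 22 mesenchymal genes 12 rose (15 rose and 1 fell adjusted over the list, median 1.47, 6.1e-07), with Stat3 at 0.93 and the filament Vim at 1.98. Of 26 PDGF receptor and kinase genes 8 rose (10 over the list, median 0.97, 0.00189), with Dusp6 at 2.53. G2/M genes fell, 29 of 34 (33 over the list, median -1.71, 1.55e-18), with the mitotic regulators Cdc20 at -2.62 and Birc5 at -2.19. These 6 lists had an adjusted p of 0.132 with an estimated correlation, and immediate early genes (16 of 25 rose, 17 over the list, median 1.96, 6.66e-08), with Egr1 at 3.97, one of 0.133.

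Between Rebound and Endpoint TAMs glycolysis genes rose as a list (11 of 30 rose and 1 fell, 16 and 1 adjusted over the list alone, median 0.85, camera adjusted p = 1.52e-05; adjusted p = 0.17 with an estimated correlation). So did interferon gamma (7 of 26 rose, 11 over the list, median 1.23, 1.07e-05; 0.346 likewise) and MHC class I (7 of 17 rose, 11 over the list, median 0.65, 0.000456; 0.347). Lysosome genes rose (9 of 32, 11 over the list, median 0.33, 0.00103; 0.403 likewise). Homeostatic microglia genes fell further (6 of 25 fell and 1 rose, 8 and 2 over the list, median -0.46, 0.00209; adjusted p = 0.416 with an estimated correlation), with the lectin Siglech at -1.93. Ribosomal protein genes (2 of 38 fell; -0.30, 0.000915; 0.534 likewise) and G1/S genes (2 of 31 fell; -0.63, 0.00311; 0.67 likewise) were lower as lists. The G1/S call was lost without Rebound 49827 (0.0686; range over alternatives 2.67e-07 to 0.67) and that of homeostatic microglia without the 3 libraries with T and NK markers (0.27; 0.000339 to 0.416). By fry their p was 0.309 and 0.0565, and that of ribosomal genes 0.138. The other 10 lists did not pass (0.0533 to 0.826), among them p53 targets (6 genes up and 2 down, 9 and 2 over the list, median 0.0556).

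**Figure D2:**
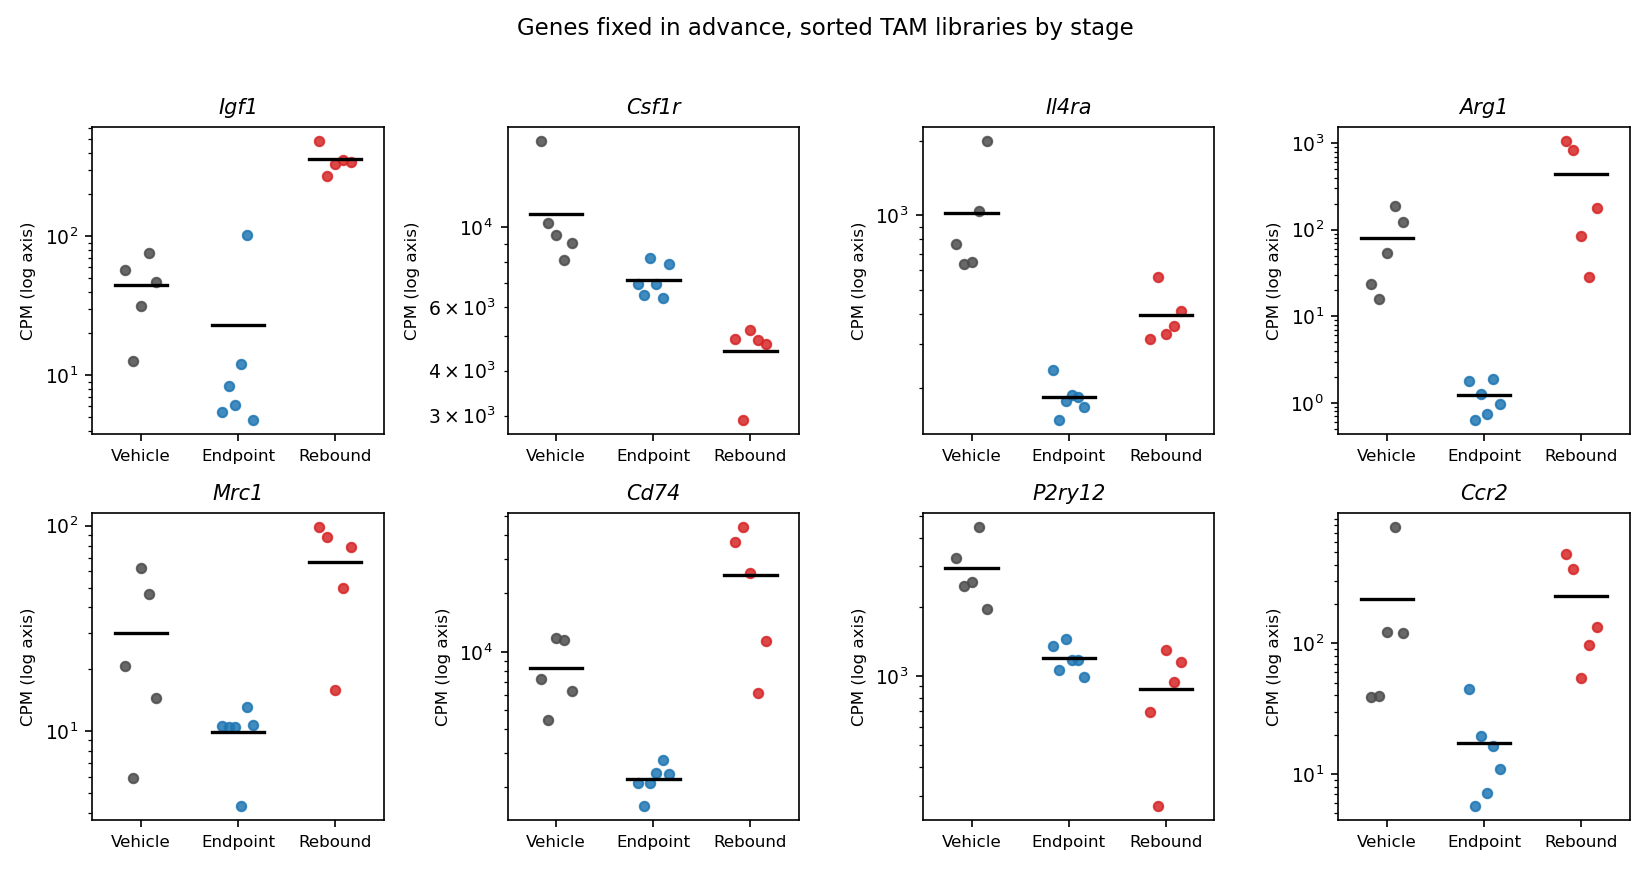
CPM (log axis) of 8 preset genes in each TAM library by stage, with a bar at the group mean. Igf1 lies at 271 to 485.8 CPM in the Rebound libraries and at 102.3 CPM in Endpoint 49843, the highest of the other TAM libraries.

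Endpoint and Vehicle TCs were compared to ask what remained in the tumour cell sort of dormant tumours. Pdgfra (chromosome 5, 75152292 to 75198215, plus strand) was 172 ± 187 CPM at Endpoint and 1989 ± 1269 CPM in Vehicle (SD, n = 6 and 5; log2 fold change -3.53, SE 0.651, edgeR adjusted p = 0.00183). Spry4, a feedback inhibitor of receptor tyrosine kinases, was 0.512 ± 0.562 against 200 ± 59.2 CPM (-8.74, SE 1.41, adjusted p = 0.000994). The peroxidase Lpo was 0.438 ± 0.46 against 78.6 ± 38.3 CPM (-7.48, SE 0.929, adjusted p = 0.000337) and the glial transcription factor Pou3f1 1.41 ± 1.24 against 55.8 ± 16 CPM (-5.26, SE 0.96, adjusted p = 0.00179). Ttr was 63460 ± 75540 against 166 ± 251 CPM (8.58, SE 2.08, adjusted p = 0.00845). Other genes abundant in the choroid plexus, Kl (9.10), the potassium channel Kcnj13 (8.64) and the folate receptor Folr1 (8.25), rose with it while choroid plexus markers were 6.83 against 1.48 log2 CPM. The T cell receptor subunit Cd3g was 494 ± 385 against 0.804 ± 0.364 CPM (9.28, adjusted p = 0.0117). The cytotoxic granule gene Nkg7 was 1073 ± 863 against 1.18 ± 1.28 CPM (9.80, 0.022), while T and NK markers were 5.16 against -0.67.

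Of 14985 genes tested between Endpoint and Vehicle TCs, 4305 were called, 2093 higher and 2212 lower. Without the 5 TC libraries with T and NK markers 1124 were called, and Pdgfra was at -2.55 (adjusted p = 0.0614; range over alternatives 1.26e-07 to 0.752), Cd3g at 1.85 (0.307; 3.5e-08 to 0.832) and Nkg7 at -0.50 (0.86). The Nkg7 call was also lost without Vehicle 57682 (0.0536) or 64247 (0.051) and with the block (0.115; range 6.76e-07 to 0.86). The receptor Igf1r was 30.8 ± 6.33 against 43.2 ± 19.2 CPM, below the Vehicle median in 6 of 6 (log2 fold change -0.49, SE 0.28, edgeR adjusted p = 0.202; -0.77 and 0.0187 by limma voom; range 0.0187 to 0.975). Mki67, a marker of cycling cells, was 76.4 ± 58.9 against 154 ± 44.7 CPM (-1.01, 0.117). Mki67 passed without Endpoint 49843 (-1.40, 0.0254), by limma voom (-1.48, 0.00325) and with the block (-1.47, 0.0164; range 0.00325 to 0.868). Csf1 was 16 ± 12.5 against 29.9 ± 9.04 CPM (-0.90, 0.159; -1.39 and 0.0276 without Endpoint 49823; range 0.0276 to 0.901). Il34 (-0.63, 0.467), the insulin receptor substrate Irs2 (-0.12, 0.855) and Pdgfb (0.04, 0.95) did not pass. The sign of Irs2 turned without Endpoint 49823 or 49825, and that of Pdgfb without 5 of the 11 libraries (down to -0.22).

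Proliferation and lineage lists fell in Endpoint TCs. Of 34 G2/M genes 28 fell (32 adjusted over the list alone, median -2.33, camera adjusted p = 1.17e-12), with Aurka at 9.27 ± 5.35 against 69.0 ± 39.1 CPM and the spindle protein Prc1 at -2.46. Of 31 G1/S genes 22 fell (25 over the list, median -1.46, 4.76e-09), with the replication factor Rfc4 at -1.79. Of 26 oligodendrocyte progenitor and proneural genes 16 fell (20 over the list, median -2.54, 7.77e-11), with Ncan at 166 ± 92.7 against 1137 ± 555 CPM and the synaptic ligand Nxph1 at -3.02. Of 21 neural stem genes 10 fell and 1 rose (10 and 1 over the list, median -1.06, 0.00243), with Sox11 at -3.31 and the fatty acid carrier Fabp7 at -2.67. These 4 lists had an adjusted p of 0.521 with an estimated correlation, and tumour cell markers were 4.80 against 8.11 log2 CPM. Of 22 cholesterol synthesis genes 12 fell (12 over the list, median -0.86, 0.00145; adjusted p = 0.545 with an estimated correlation), with the decarboxylase Mvd at -1.62.

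Immune and lysosomal lists rose in Endpoint TCs, where myeloid markers were 7.51 against 5.77 log2 CPM. Of 32 lysosome genes 17 rose and 1 fell (20 and 1 adjusted over the list alone, median 1.17, camera adjusted p = 4.71e-06), with the saposin precursor Psap at 1508 ± 1123 against 244 ± 56.0 CPM. Of 21 TGF-beta genes 7 rose and 1 fell (9 and 1 over the list, median 0.86, 0.0111), with the receptor Tgfbr1 at 1.62 (adjusted p = 0.521 with an estimated correlation for both). Of 17 MHC class I genes 10 rose (15 over the list, median 2.51, 4.71e-06), with B2m at 2857 ± 1223 against 501 ± 230 CPM. Of 16 IL-4 and STAT6 genes 8 rose and 1 fell (9 and 1 over the list, median 1.89, 0.0276), with the receptor subunit Il13ra1 at 2.17 (0.545 likewise for both). Homeostatic microglia genes (9 of 25 rose and 1 fell, 12 and 1 over the list, median 1.38, 0.00145), with Tmem119 at 2.03, rose. So did interferon gamma (6 of 26, 6 over the list, median 1.75, 0.00145), type I interferon (3 of 33, none adjusted over the list, median 1.23, 0.007) and MHC class II genes (1 of 12, 1 over the list, median 1.94, 0.0117), each with an adjusted p of 0.57 with an estimated correlation. Without the 5 libraries with T and NK markers the medians were -0.41 for IL-4 (adjusted p = 0.96; range over alternatives 0.0108 to 0.96), -0.40 for type I interferon (0.903; 0.000345 to 0.903), -0.67 for interferon gamma (0.906; 1.1e-05 to 0.906) and 1.64 for MHC class II (0.133; 0.00426 to 0.57). That omission leaves only Endpoint 49843 and 49845. The IL-4 call was also lost without Vehicle 54363, 57098 or 64247 (0.0682, 0.0657 and 0.0529) and with the block (0.0796). Without genes of the other cell type the medians were 1.53 for IL-4 (0.353), 0.58 for type I interferon (0.12), 1.19 for interferon gamma (0.0798) and 0.79 for TGF-beta (0.0769; 0.00106 to 0.521). By fry the p was 0.142 for type I interferon, 0.101 for interferon gamma, 0.0673 for MHC class II and 0.0514 for homeostatic genes. The other 18 lists did not pass (0.105 to 0.678), with 11 of 22 p53 targets down and 5 up (11 and 6 over the list, median 0.198).

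Rebound TCs differed from Vehicle TCs in few single genes: edgeR called 11 of 14985, 6 higher and 5 lower. The fibrillar collagens Col1a1 (chromosome 11, 94936224 to 94953042, plus strand) and Col3a1 were 439 ± 519 against 2.71 ± 2.68 CPM and 802 ± 966 against 16 ± 11.2 CPM (SD, n = 5 each; log2 fold changes 7.32 and 5.64, SE 1.19 and 0.978, edgeR adjusted p = 0.0308 and 0.0443). The basement membrane protein Nid1 was 197 ± 205 against 9.20 ± 1.13 CPM (4.42, SE 0.706, adjusted p = 0.0308). The retinoic acid synthesis enzyme Aldh1a2 was 64.5 ± 59.1 against 2.81 ± 0.884 CPM (4.51, SE 0.74) and the lipocalin Apod 994 ± 708 against 107 ± 38.6 CPM (3.22, SE 0.461), both at an adjusted p of 0.0308. The prefoldin subunit Pfdn1 (-1.50, 0.0308), the microRNA gene Mir682 (-2.18, 0.0379) and Foxred1 (-1.15, 0.0443) were lower. Pericyte and fibroblast markers averaged 5.43 ± 1.48 against 2.65 ± 1.02 log2 CPM in these libraries (exact permutation test, adjusted p = 0.0687) and myeloid markers 2.90 ± 2.23 against 5.77 ± 1.18 (0.0794).

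The count of 11 depended on single TC libraries. It was 0, 0, 7, 3 and 0 without Vehicle 54359, 54363, 57098, 57682 and 64247 and 1, 2, 0, 586 and 5 without Rebound 49041, 49059, 49692, 49827 and 49849. It was 320 without the 5 libraries with T and NK markers, 600 by DESeq2, 1447 by limma voom and 1177 with the block. Without Vehicle 54359 the adjusted p was 0.127 for Col1a1 (range over alternatives 9.13e-15 to 0.415), 0.154 for Col3a1 (1.54e-10 to 0.458), 0.123 for Nid1 (1.03e-09 to 0.485) and 0.123 for Aldh1a2 (5.72e-09 to 0.489). It was 0.0951 for Apod (1.03e-09 to 0.297), 0.116 for Pfdn1 (9.22e-06 to 0.45), 0.116 for Mir682 (9.22e-06 to 0.415) and 0.121 for Foxred1 (9.39e-06 to 0.453). Each of these 8 genes missed without 5 to 9 of the 10 libraries, Col3a1 without 9 (0.0606 to 0.154). With one library left out the log2 fold changes were 6.32 to 8.125 for Col1a1, 4.60 to 6.09 for Col3a1, -1.67 to -1.37 for Pfdn1 and -1.23 to -1.10 for Foxred1.

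Of the preset genes in Rebound against Vehicle TCs, Igf1r was 67.2 ± 12.7 against 43.2 ± 19.2 CPM, higher in 4 of 5 (log2 fold change 0.64, SE 0.293, edgeR adjusted p = 0.319). Il34, the other ligand of CSF-1R, was 39.5 ± 33.4 against 8.60 ± 3.22 CPM, higher in 4 of 5 (2.20, SE 0.667, adjusted p = 0.173; 2.49 and 0.0212 without Rebound 49827; 1.83 and 0.0467 with the block; range over alternatives 0.0121 to 0.967). Mki67 (1.02, 0.344), Pdgfb (0.73, 0.39), Csf1 (0.65, 0.563), Irs2 (0.40, 0.718) and Pdgfra (-0.08, 0.974) did not pass in edgeR. Limma voom called Mki67 (1.11, 0.031) and Pdgfb (1.04, 0.0188), with up to 0.758 and 0.948 over alternatives. The sign of Pdgfra turned without Vehicle 57098 or 57682 or Rebound 49827 (0.08, 0.26 and 0.16).

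By list, 12 of 31 passed in Rebound against Vehicle TCs. Of 30 matrix genes 2 rose, Col1a1 and Col3a1 (21 adjusted over the list alone, median 2.83, camera adjusted p = 9.69e-15; adjusted p = 0.273 with an estimated correlation). The 16 IGF system genes rose as a list (3 over the list, median 0.54, 0.00494; adjusted p = 0.257 with an estimated correlation). Glycolysis fell (15 of 30 over the list, median -1.07, 9.27e-13; adjusted p = 0.135 with an estimated correlation). Oxidative phosphorylation (24 of 38 over the list, median -0.77, 8.77e-14), ribosomal proteins (18 of 38; -0.75, 9.56e-15), homeostatic microglia (5 of 25; -1.50, 8.14e-07) and immediate early genes (-0.32, 0.0204) fell as lists with an adjusted p of 0.531 with an estimated correlation. Cholesterol synthesis (1 of 22 over the list, median -0.37, 0.00327) fell with one of 0.57. Interferon gamma (0.81, 0.00922) and MHC class I (1.12, 0.0113) were higher, with an adjusted p of 0.77 and 0.752 with an estimated correlation, and MHC class II (-0.02, 0.0113) and disease-associated microglia (-0.15, 0.0399) lower, at 0.648 for both. Col1a1 and Col3a1 were the only list members called over all genes.

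By fry 3 of these TC lists passed: matrix, IGF and glycolysis. Calls for 6 were lost without single libraries. Interferon gamma and MHC class I had medians of 0.33 (camera adjusted p = 0.128) and 0.60 (0.348) without Rebound 49827, where T and NK markers were 7.515 log2 CPM against at most 0.196 in the other Rebound TCs. The medians were 0.30 (0.0698) and 0.60 (0.24) without the 5 libraries with T and NK markers and 0.57 (0.205) and 0.99 (0.263) without genes of the other cell type. Both calls were also lost without Rebound 49059 (0.095 and 0.0833) and with the block (0.065 and 0.0546; ranges over alternatives 1.21e-05 to 0.77 and 6.15e-05 to 0.752). MHC class II was at 0.0597 and 0.111 without Rebound 49692 and 49849 (1.79e-06 to 0.648) with medians of 0.17 and 0.26, and cholesterol at 0.0772 and 0.128 without Vehicle 57098 and Rebound 49827 and 0.1 without the 5 (1.48e-05 to 0.57). Disease-associated microglia genes were at 0.0883 to 0.171 without 4 of the 10 libraries, 0.383 without genes of the other cell type and 0.0924 with the block (0.00781 to 0.648). Immediate early genes were at 0.0605 to 0.0975 without 4 libraries, 0.0884 without genes of the other cell type, 0.0579 without the 5, 0.0699 with halved counts and 0.0546 with the block (0.000596 to 0.531). The 19 lists that did not pass (0.0689 to 0.995) included G2/M (median 0.07, 0.942) and oligodendrocyte progenitor genes (0.18, 0.242), while tumour cell markers were 8.22 against 8.11 log2 CPM.

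Rebound TCs were compared with Endpoint TCs to ask what distinguished Rebound from dormant tumours in this sort. Igf1r was 67.2 ± 12.7 CPM at Rebound and 30.8 ± 6.33 CPM at Endpoint (SD, n = 5 and 6; log2 fold change 1.13, SE 0.281, edgeR adjusted p = 0.00939). Pdgfra rose from 172 ± 187 to 1884 ± 899 CPM (3.45, SE 0.649, adjusted p = 0.0023). Mki67 rose from 76.4 ± 58.9 to 312 ± 127 CPM (2.03, SE 0.479, adjusted p = 0.00718) and Il34 from 5.52 ± 3.58 to 39.5 ± 33.4 CPM in 4 of 5 (2.84, SE 0.643, adjusted p = 0.00582). Spry4 was 133 ± 252 against 0.512 ± 0.562 CPM (8.15, 0.00152), Lpo 158 ± 167 against 0.438 ± 0.46 CPM (8.49, 0.000347). The matrix protein Tnc was 339 ± 215 against 5.87 ± 10.3 CPM (5.93, 0.00281) and the chromatin protein Hmga2 89.1 ± 71.4 against 2.61 ± 5.74 CPM (5.29, 0.00963). Ttr fell from 63460 ± 75540 to 412 ± 534 CPM (-7.27, 0.0153) with Folr1 (-7.17), Kl (-6.57) and Kcnj13 (-6.35), while choroid plexus markers were 1.41 against 6.83 log2 CPM. Csf1 rose by 1.55 (0.0242), a call lost without Endpoint 49831 (0.0512) or Rebound 49059 (0.106; range over alternatives 0.00407 to 0.998); Irs2 (0.53, 0.373) and Pdgfb (0.69, 0.172) did not pass in edgeR. By limma voom both passed (1.20, 0.0107, and 0.90, 0.0143; up to 0.998 over alternatives), as did Pdgfb without the 5 libraries with T and NK markers (1.53, 0.0462).

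Of 14985 genes 3758 were called between Rebound and Endpoint TCs, 2041 higher and 1717 lower. Without the 5 libraries with T and NK markers, which leave 2 Endpoint mice, the adjusted p was 0.137 for Igf1r (1.02; range over alternatives 0.000181 to 0.998), 0.0586 for Mki67 (1.97; 6.58e-06 to 0.998) and 0.0573 for Hmga2 (4.03; 0.000105 to 0.94). Of 34 G2/M genes 31 rose (34 adjusted over the list alone, median 2.38, camera adjusted p = 1.45e-12), with Plk1 at 82.7 ± 41.8 against 9.71 ± 8.88 CPM and Aurka at 2.85. Of 31 G1/S genes 19 rose (26 over the list, median 1.18, 3.17e-08), with the replication helicase Mcm2 at 1.82 (adjusted p = 0.53 with an estimated correlation for both). Of 26 oligodendrocyte progenitor genes 20 rose (22 over the list, median 2.91, 1.45e-12), with Ptprz1 at 2.90 and Nxph1 at 4.03. Of 21 neural stem genes 10 rose and 1 fell (10 and 1 over the list, median 1.17, 0.00351), with Sox11 at 3.37 and Tubb3 at 2.53 (0.518 likewise for both), while tumour cell markers were 8.22 against 4.80 log2 CPM. Of 30 matrix genes 11 rose (13 over the list, median 1.42, 0.00351; adjusted p = 0.594 with an estimated correlation), with Postn at 4.59 and the laminin Lama4 at 4.22. Pericyte and fibroblast markers were 5.43 ± 1.48 against 3.38 ± 0.43 (adjusted exact p = 0.0362).

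By camera 11 lists were lower in Rebound than in Endpoint TCs, where myeloid markers were 7.51 and 2.90 log2 CPM. Of 25 homeostatic microglia genes 16 fell and 1 rose (19 and 1 adjusted over the list alone, median -2.79, camera adjusted p = 5.2e-09), with the transcription factor Mef2c at -2.31. Of 32 lysosome genes 20 fell and 1 rose (21 and 1 over the list, median -1.32, 2.19e-07), each with an adjusted p of 0.518 with an estimated correlation. Of 12 MHC class II genes 5 fell (5 over the list, median -2.13, 0.000109; adjusted p = 0.53 with an estimated correlation), with H2-DMa at -1.79. Oxidative phosphorylation (22 of 38 fell, 28 over the list, median -0.84, 3.7e-08), with Ndufa1 at -1.90 and Cox6a1 at -1.23, fell. So did ribosomal proteins (7 of 38, 13 over the list, median -0.67, 0.000105), glycolysis (7 of 30, 10 over the list, median -0.53, 0.00876), with Pdk1 at -2.08 and Aldoa at -1.34, and MHC class I (4 of 17, 4 over the list, median -1.24, 0.00265). These 4 lists had an adjusted p of 0.594 with an estimated correlation. The same estimated-correlation p of 0.594 went with disease-associated microglia (8 of 26 fell and 3 rose, 8 and 3 over the list, median -0.91, 0.0312), with Ctsd at -2.59 and Cd68 at -3.54. It also went with monocyte-derived (1 of 24 rose, 1 over the list, median -1.50, 0.0255) and inflammatory genes (1 of 24 rose and 1 fell, 1 and 1 over the list, median -1.20, 0.0191), with Nfkbia at -1.18. Type I interferon genes (2 of 33 fell and 1 rose, 1 fell adjusted over the list, median -1.24, 0.00351; adjusted p = 0.626 with an estimated correlation), with Rsad2 at -3.08, fell as a list.

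The call for disease-associated microglia in Rebound against Endpoint TCs was lost without Endpoint 49843 (camera adjusted p = 0.171) or Rebound 49849 (0.07; range over alternatives 0.00059 to 0.74), and that for monocyte-derived genes with the block (0.14; 0.00364 to 0.594). Without the 5 libraries with T and NK markers (marker means 0.78 at Rebound and 5.16 at Endpoint) the MHC class I median was 0.21 (camera adjusted p = 0.273; range 0.000134 to 0.594). Then type I interferon (-0.25, 0.551; 0.00012 to 0.626), monocyte-derived (-0.66, 0.31) and inflammatory genes (-0.73, 0.0654; 0.00349 to 0.65) also missed. Without genes of the other cell type the medians were -0.77 for lysosome (0.111; 2.45e-10 to 0.518), -0.25 for disease-associated (0.74), -0.55 for inflammatory (0.65), -1.39 for monocyte-derived (0.165), -0.87 for type I interferon (0.08) and -0.95 for MHC class I genes (0.0584). By fry the p was 0.051 for inflammatory, 0.0592 for monocyte-derived and ribosomal, 0.127 for type I interferon, 0.0757 for MHC class I and 0.0553 for matrix genes. The 15 lists that did not pass (0.0593 to 0.972) included the unfolded protein response, with 5 genes down and 1 up (median 0.256).

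**Figure D3:**
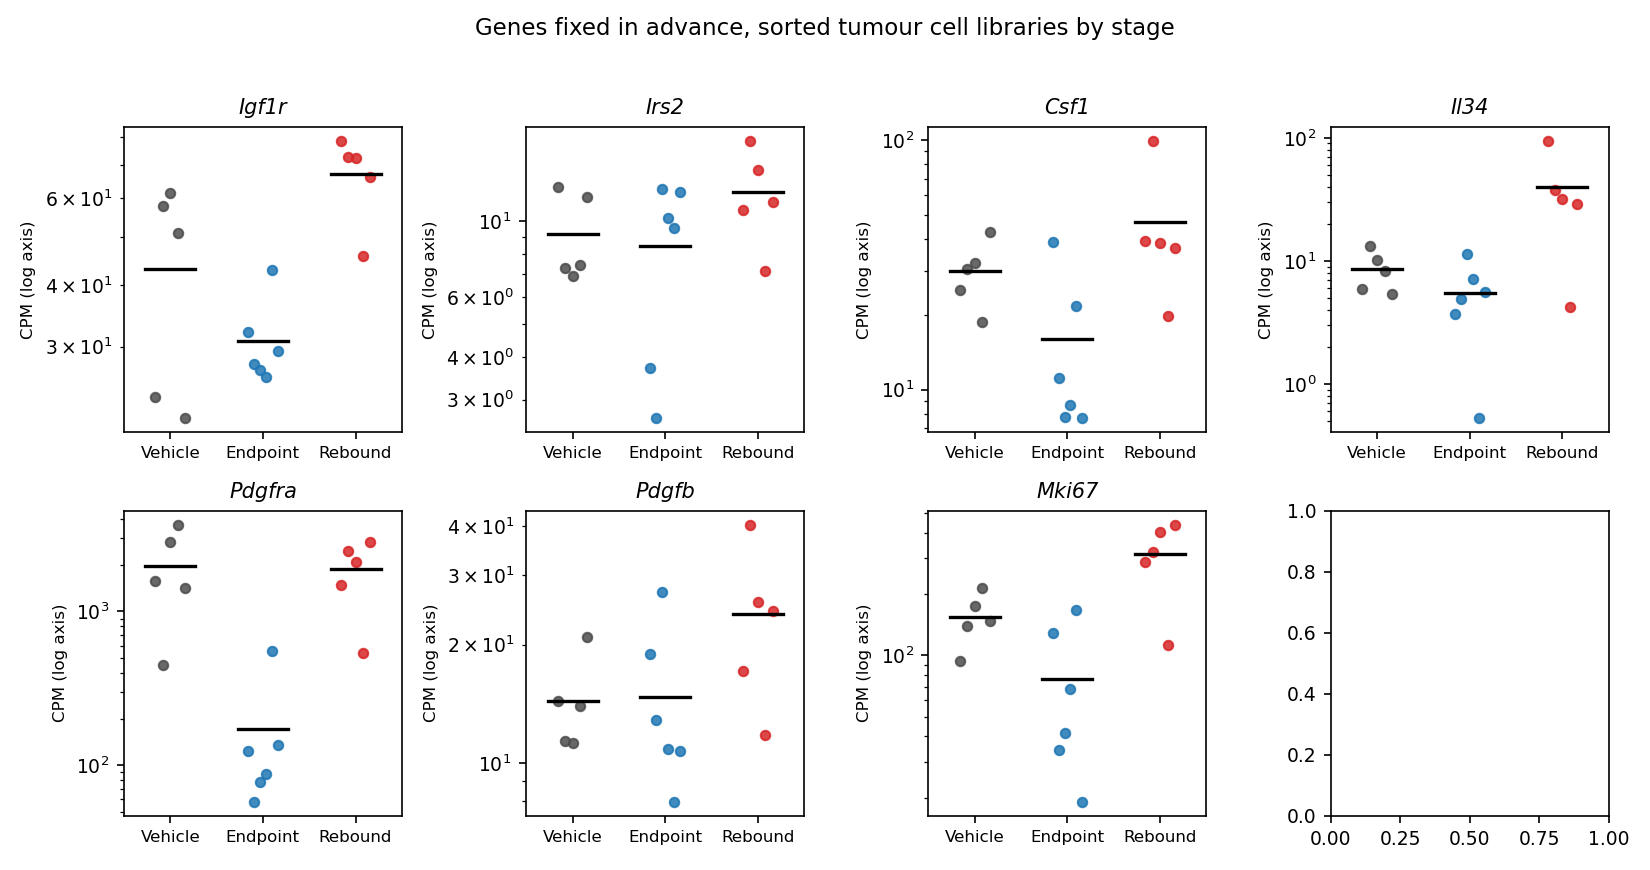
CPM (log axis) of 7 preset genes in each TC library by stage, with a bar at the group mean. Pdgfra averaged 172 CPM at Endpoint against 1989 in Vehicle and 1884 at Rebound.

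Whether TAM Igf1 went with tumour cell features was examined across the 15 mice with both libraries, with 3 relations tested. TAM Igf1 and TC Igf1r correlated with r = 0.643 (permutation p = 0.0121, adjusted 0.0182) and rho = 0.582 (0.0261, adjusted 0.0392). TAM Igf1 and the mean of the TC G2/M list correlated with r = 0.693 (0.00533, adjusted 0.016) and rho = 0.679 (0.00712, adjusted 0.0214). Its relation to the TC FOXO-induced list had r = 0.0452 (permutation p = 0.87) and rho = 0.0643 (0.822). Without the 2 mice farthest from the median of TAM Igf1, Rebound 49041 and Endpoint 49845, r was 0.548 for Igf1r and 0.609 for G2/M (adjusted permutation p = 0.0836 for both) and -0.368 for FOXO. With stage means removed r was 0.0694 for Igf1r (permutation p = 0.81) and 0.56 for G2/M (0.0372, adjusted 0.112). Within the 6 Endpoint mice r was 0.797 (exact permutation p = 0.157) and rho -0.0286 for Igf1r, 0.787 (0.0667) and 0.6 for G2/M and 0.249 (0.53) for FOXO; Vehicle and Rebound hold fewer than 6 pairs.

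The 2 contrasts with Vehicle share their controls, and their overlap was set beside chance values. In TAMs 505 genes were higher and 750 lower in both Endpoint and Rebound, and 34 moved in opposite directions. Independent lists would share 127.5 and 198.5. Unchanged groups simulated on these controls had almost no calls, so their 0 shared is no test. With the Vehicle mice split between the contrasts, the medians over 20 splits were 133.5 (39 to 306) and 314 (74 to 542). The covariance of log2 fold changes was 0.336 against a simulated 0.122 and their correlation 0.339 against 0.515. In TCs 5 genes were higher and 5 lower in both, against 0.838 and 0.738 for independent lists. With split controls the median was 0, but the median number of Rebound calls was itself 0 in each direction. The covariance was 0.942 against a simulated 0.27 and the correlation 0.448 against 0.511.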

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

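In this part, all tests of explanations but thinning, and the counts of other sample splits, were chosen only after their results were seen.

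In 135 groups of 5 or 6 libraries, 13 held a library far from the others, and chance gives about 1 in 20 groups. Igf1 was 6.679 log2 CPM in TAM Endpoint 49843 against 2.283 to 3.596 in the other TAM Endpoint libraries, and the TC library of that mouse had tumour cell markers at 7.418 against 4.072 to 4.557 and an Rn45s share of 4.079 log2 percent against 2.666 to 2.963. Mrc1 was 2.143 in TAM Endpoint 49831 (others 3.405 to 3.718), Csf1r 11.51 in TAM Rebound 49059 (12.21 to 12.34) and erythroid markers -0.1774 in TAM Endpoint 49823 (-1.118 to -0.7993). Endothelial markers were -0.3876 in TAM Rebound 49827 (1.232 to 1.735), neutrophil markers -1.739 in TC Vehicle 57682 (0.2358 to 0.9472) and pericyte and fibroblast markers 2.585 in TC Endpoint 49845 (3.371 to 3.777). TC Rebound 49827 stood apart in myeloid (6.854; others 1.582 to 2.4), T and NK (7.515; -1.676 to 0.196), B (1.836; -2.808 to -1.762) and dendritic cell markers (3.218; -0.245 to 0.691).

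The stage contrasts differed between TAM and TC, tested by edgeR as an interaction. In Endpoint against Vehicle 4025 genes differed, 1368 higher and 2657 lower in TAM relative to TC, among them Igf1 (-3.309, adjusted p = 0.0183), Il4ra (-4.177, 4.8e-05), Arg1 (-5.946, 0.000276), Cd74 (-4.411, 0.00278), Ccr2 (-9.318, 0.00141), Csf1 (-2.399, 0.00821) and Mki67 (2.181, 0.0149). In TC Endpoint, Ccr2 was 150.9 to 287.6 CPM in the 4 libraries with T and NK markers above 5 and 1.499 and 8.483 CPM in the other 2. In Rebound against Endpoint 3225 differed, 2100 higher and 1125 lower: Igf1 by 5.225 (adjusted p = 0.00109), Csf1r 3.921 (0.00401), Il4ra 2.486 (0.00607), Arg1 8.592 (3.06e-05), Cd74 5.316 (0.000964), P2ry12 3.038 (0.0146), Ccr2 5.97 (0.0225) and Mki67 -4.096 (0.00018). Csf1r fell in TAM (-0.66), while myeloid markers in TC went from 7.507 to 2.895 log2 CPM. In Rebound against Vehicle 81 differed, 50 higher and 31 lower; without single libraries the count was 51 (TAM Rebound 49059), 36 (TAM Rebound 49834), 41 (TC Vehicle 54359), 49 (TC Rebound 49059), 50 (TC Rebound 49692) and 605 (TC Rebound 49827), and it was 4 with the mouse as a block.

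The first pattern weighed is that TC Endpoint libraries hold choroid plexus markers and fewer tumour cell transcripts. A lower share of tumour cells alone would raise other markers alike, but rises ranged from 5.828 for T and NK markers to -0.2261 for neutrophil markers, 6.055 apart. Thinning TC Vehicle to 4.18 M counts left tumour markers -3.245 apart, but thinning keeps CPM, so depth stays open. RNA from choroid plexus cells cannot be told apart from a change in the sorted cells: the 8 of 9 markers over 2-fold higher are the pattern itself. A loss of PDGFRA-bearing cells was not tested.

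The second is that Endpoint and Vehicle TAMs differ in 4390 genes. TAM and TC log2 fold changes correlated by 0.00717 over 12863 genes (770 called alike, 496 opposite). As TC cell content also changed, a gene by gene counting difference stays open. Halving the BLZ945 counts left 4473 calls, 4287 of them among the 4390, but scaling removes a common factor, so paired counting stays open. Mouse cohorts cannot be told apart from treatment, since 0 vehicle mice carry numbers within the range of the BLZ945 mice. Treatment stays open beside them.

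The third is the higher Igf1 of Rebound TAMs. The highest Igf1 of any TC library was 27.04 CPM against 271 for the lowest Rebound TAM library, which argues against RNA from the tumour cell sort. The 2 Rebound TAM libraries with T and NK marker means below 0 held at least 329.5 CPM, above the highest Endpoint library at 102.3 CPM, which argues against T and NK cells. A larger share of monocyte-derived cells cannot be told apart from a change within cells: that list had a median of 0.723 and an adjusted p of 0.0659 by camera. Regrowth of the tumour stays open as a biological explanation and may act with it.

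Other splits of the same libraries into groups of the same sizes (100 for each result, the real one included) asked whether chance can be excluded for the counts. It can for TAM Endpoint versus Vehicle (1 split with as many calls; real 4390, highest other 1), TAM Rebound versus Vehicle (1; 1961, 107), TAM Rebound versus Endpoint (1; 2337, 378), TC Endpoint versus Vehicle (1; 4305, 841), TC Rebound versus Endpoint (1; 3758, 1926) and TAM versus TC (1; 10714, 7145). It can also for the differences between TAM and TC in Endpoint versus Vehicle (1 split, 4025, 1854) and Rebound versus Endpoint (1 split, 3225, 1013). It cannot for the difference in Rebound versus Vehicle (4 splits, 81, 656), where the count was 4 with the mouse as a block. Nor can it for TC Rebound versus Vehicle (5 splits, 11, 839). In these last 2 the highest other count was several times the real one, and the cause of this was not tested. For list calls chance cannot be excluded in any contrast. In TAM 10 splits had as many in Endpoint versus Vehicle (15, highest other 17, median other 10). Rebound versus Vehicle had 47 (13, 18, 12) and Rebound versus Endpoint 9 (21, 22, 15). In TC it was 20 (13, 20, 10), 40 (12, 21, 10) and 10 (16, 19, 10), in this order.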

How the results depend on the processing

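The mouse block for lists, the halved counts, the marker covariates and the omission of 3 TAM or 5 TC libraries were tests chosen only after the data were seen. With an estimated correlation 0 lists were called in each of the 6 contrasts by camera, and in TC Rebound versus Vehicle fry called 3 against 12. An absolute log2 fold change of at least 1 left 2257, 909 and 1506 genes in TAM Endpoint versus Vehicle, Rebound versus Vehicle and Rebound versus Endpoint. A fit of 2 stages gave 999 in TAM Rebound versus Vehicle and 0 in TC Rebound versus Vehicle, where edgeR with 3 stages called 11 (2243 at an unadjusted p below 0.05), DESeq2 600, limma voom 1447, the stricter filter 26, robust=FALSE 20, removal of genes of the other cell type 22 and halved counts 25. Limma voom called 7461 genes in TC Endpoint versus Vehicle and 8612 in TC Rebound versus Endpoint. Without genes of the other cell type 7, 6 and 8 lists were called in TC. Without the 3 TAM libraries 525 genes were called in Rebound versus Vehicle and 592 in Rebound versus Endpoint, and without the 5 TC libraries 1124 in Endpoint versus Vehicle and 320 in Rebound versus Vehicle. With covariates these were 159 and 59 in TAM and 0 in each of the 3 TC contrasts by edgeR, where the 3 marker means themselves follow stage. All 32 libraries in one fit gave 1094 and 1416 in the TAM Rebound contrasts and 670 in TC Rebound versus Vehicle. The limma fit of all 32 libraries with the mouse block, which changes the tool and the fit too, gave 1050 and 1180 in the TAM Rebound contrasts. It gave 1177 in TC Rebound versus Vehicle and 6643 in TC Rebound versus Endpoint. Of the named genes and lists this limma fit ended 16 and 9 calls and added 3, each also called by voom without the block. For the difference between TAM and TC in Rebound versus Vehicle, edgeR with the mouse as a fixed factor gave 4, DESeq2 374 and voom 478. For that in Rebound versus Endpoint voom gave 6940. For named genes the covariates ended 119 calls and turned 19 signs, and the joint fit ended 23 calls.

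With one library left out, counts were 3670 to 4360, 1394 to 2138 and 1624 to 2556 in the TAM contrasts and 3217 to 4929, 0 to 586 and 2541 to 5618 in the TC contrasts, 10535 to 10785 in TAM versus TC and 3473 to 4656, 36 to 605 and 2472 to 4549 for the differences. List counts were 13 to 17, 10 to 16 and 21 to 23 in TAM and 12 to 16, 9 to 12 and 15 to 18 in TC. Of 219 results for named genes 194 kept direction and side of the threshold under every omission, and of 90 called lists 75.

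Signs turned for Ccr2 in TAM Rebound versus Vehicle (-0.42 to 1.52 with one library left out, -1.55 without the 3 libraries, -0.67 with covariates, -0.015 in the joint fit), and without the 3 libraries for Arg1 (-0.54) and the immediate early list (-0.14). P2ry12 was 0.34 in TAM Rebound versus Endpoint with covariates. In TC Endpoint versus Vehicle, Pdgfb was -0.055 without a filter, -0.035 with the block, -0.63 without the 5 libraries and -0.22 to 0.21 with one left out; Irs2 was 0.24 without the 5, 1.00 with covariates and -0.28 to 0.069 with one left out; Nkg7 was -0.50 and the type I interferon list -0.40 without the 5. Covariates turned Nkg7 (-3.00), Ltc4s (-1.23), Stat6 (-0.30), Ttr (-0.98) and Mki67 (0.63). In TC Rebound versus Vehicle, Pdgfra was 0.16 without the 5, 0.11 with covariates, 0.019 with the block and -0.33 to 0.26 with one left out; covariates turned Il34 (-0.31) and Pdgfb (-0.22). In TC Rebound versus Endpoint covariates turned Cd68 (0.17), Cox6a1 (0.050), Irs2 (-0.19), Kl (0.74), Pdgfb (-0.54), Psme1 (0.071), Tapbp (0.41) and Ttr (1.05). Across mice, r for Igf1r was 0.548 without 2 mice and 0.0694 with stage means removed, for G2/M 0.609 and 0.56, and for FOXO -0.00852 with RLE and -0.368 without 2 mice. The cause was not tested, except that fewer libraries or genes entered some fits. Depth was lowest in TC Endpoint (4.18 to 14.0 M). What else it limits was not tested apart from the spread between mice.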

Other observations

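No test in this part was chosen only after its result was seen, but the pattern behind the hypothesis was noticed in the same data. Other genes of the brain also moved in the TC libraries. Astrocyte markers averaged 8.47 ± 0.14 log2 CPM at Endpoint (n = 6) against 7.38 ± 0.88 in Vehicle (n = 5; exact permutation test, adjusted p = 0.0337) and 5.66 ± 1.51 at Rebound (n = 5; 0.0187). Myelinating oligodendrocyte markers were 6.53 ± 0.25 at Endpoint and 5.62 ± 0.49 in Vehicle (adjusted exact p = 0.0187), and neuron markers 4.71 ± 0.16 at Endpoint and 1.90 ± 1.72 at Rebound (0.0362). Id1, a target of BMP signalling, rose in 6 of 6 Endpoint TCs, from 14.3 ± 7.44 to 81.8 ± 43.5 CPM (log2 fold change 2.52, edgeR adjusted p = 0.00417). In TAMs the interleukin 7 receptor Il7r fell from 99 ± 29.1 CPM at Endpoint to 16.3 ± 8.19 CPM at Rebound in 5 of 5 (-2.60, 0.000612).

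In Endpoint mouse 49843, TAM Igf1 was 102.3 CPM and the TC library held tumour cell markers at 7.418 log2 CPM, both apart from the other Endpoint mice. A hypothesis from this mouse is that TAM Igf1 follows the amount of tumour cell RNA in the TC library. Over the 15 mice with both libraries and with stage means removed, Spearman's rho was 0.6571 (permutation p = 0.009; 0.0125 with mice permuted within stages) and Pearson's r 0.858 (0.00093). Without the farthest mice, Endpoint 49843 and Vehicle 54363, r was 0.54 (permutation p = 0.0584), but stage means still held both. This leaves the hypothesis open, with its mouse among the 15. A mouse whose tumour had begun to regrow could give the same values, and no label records tumour size.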
